A study of Oryza sativa with 2 samples.

How the data were processed

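Total RNA from leaves of 6-week-old rice plants, 10 plants per genotype, grown in a greenhouse at 28 °C with 14 h light and 10 h dark, was measured on the Affymetrix rice GeneChip. Per the labels' protocols, RNA was purified on RNeasy columns, its integrity was checked on a Bioanalyzer, and biotin-labelled cRNA was made with a 3' IVT Express kit, which starts at the poly-A tail. There were 2 arrays, 1 of the control 9311 and 1 of the LRK1 transgenic plants in 9311. The groups were taken from the genotype labels.

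The deposited values are log2 signals, 1 per probe set and array, made with MAS5 per the submitters' processing notes. The version of MAS5, the scaling target and any floor are not given in the sources used here. The scale was read from the values, which run from 0 to 16.24, and signals at the lowest value are listed at 0, for 883 probe sets on the control array and 230 on the transgenic array. Detection calls were not used here. MAS5 can bring each array to a common level, in which case a change shared by most transcripts would not be seen. Whether these arrays share a target is not known, since their medians differ (5.21 and 5.56) and the spikes were 0.34 higher on the transgenic array. Probe sets near background are noisy on the log2 scale. Labelling from the poly-A tail weights the 3' end of transcripts, so differences in RNA integrity can change signals.

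Of 57381 probe sets, 123 were array controls and were kept out of the comparison. Genes were assigned through the platform's annotation and named through the gene table of assembly ASM3414082v1 of Oryza sativa Japonica, of which no coordinates are printed. Of the other 57258 probe sets, 22436 had 1 gene, 95 had several and were given no name, and 34727 had no gene in the table used. All 17905 genes with a probe set were found in the current gene table. A gene with several probe sets was represented by the one with the highest mean log2 signal. In 1951 genes with at least 2 measured probe sets, the ratios of the first 2 correlated with r = 0.648 across genes and differed with an SD of 0.695, and of 349 genes whose first probe set was past 2-fold, 308 (88.3%) had the second in the same direction and 169 also past 2-fold.

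The floor was the median log2 signal of all probe sets other than controls over both arrays, 5.40, a linear signal of 42.1. A probe set was called higher or lower where both signals reached the floor and differed at least 2-fold. It was called above the floor on 1 array only where that signal was at least 2 times the floor and the other below it, and its fold is then a bound, signal over floor, written as "at least". No test was run. For gene lists, 15150 genes with at least 1 array at the floor entered, signals below the floor were set to it, and a list needed 5 genes. A list's median log2 ratio was placed among 10000 random lists of the same size matched in 20 bins of mean signal, and stood apart at or below percentile 2.5 or at or above 97.5. These percentiles describe these arrays only.

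The size rule, the floor, the rule for named genes, 36 list themes and the alternatives were fixed before the data were examined. Those lists were written by gene title, and the gene tables used here hold symbols, so 33 themes were rebuilt from symbols and 9 lists were added from the name tables, before any ratio was seen. The other 3 planned themes, plastid ribosomal proteins, NLR immune receptors and transposon-derived genes, had no members by symbol and were not tested. Neither was the LRK cluster theme, which is among the 33 but held 0 genes. Another 8 lists were chosen after the ratios were seen and appear only among the closing observations. Named genes were the 10 highest and 10 lowest ratios among genes with a usable symbol measured on both arrays, the 5 highest bounds in each direction, and up to 2 members per direction of each list, or the brightest member where none passed the rule. The planned rule asked for an informative title, and a usable symbol or synonym took its place, which left 2136 of the entering genes with a name. Genes named outside the rule are said to be so. Some named genes rest on probe sets ending in _x_at or _s_at, which can bind several transcripts. Among these are MADS14, D11, PIN3A, LOGL1, HAK1, OsCASP1, CYP701A19, SGR and FNR (LOC4342399). Their folds may thus not be specific to the gene. LRK1 could not be tied to a probe set, because none of the names in the gene table contains LRK.

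Control probe sets gave the array quality. Bacterial spikes, 63 probe sets, had a median log2 ratio of 0.34 with an SD of 0.220 across probe sets. The 27 hybridisation spikes, all higher on the transgenic array, had a median of 0.37, and the 36 poly-A spikes, 30 of them higher, had 0.26. All 6 Trp spike probe sets were below the floor on both arrays. The ratio of 3' to 5' signal was 9.45 on the control and 6.95 on the transgenic array for actin, 16.4 and 16.2 for the other actin pair, 3.87 and 2.16 for GAPDH, 2.05 and 1.62 for cyclophilin, and 0.831 and 0.782 for ubiquitin.

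Alternatives were centring on the median ratio, quantile normalization, loess of ratio on mean signal with a span of 0.3, the floor at the 25th and 75th percentile, leaving out probe sets whose names end in _x_at or _s_at and can bind several transcripts, size rules of 1.5-fold and 3-fold, counting genes, the median over a gene's probe sets, only genes measured on both arrays, and log2(signal + 16) without a floor. Centring on the bacterial spikes and matching random lists on signal and genomic span were added after seeing the data. The steps were tested on simulated data for this comparison, with 17905 genes and an assumed noise SD of 0.3. In both noise settings the shifted genes were drawn from those at least 2.5 above the floor on the control array. Recovery of genes nearer the floor was thus not tested. The 2-fold rule recovered 48 of 50 genes shifted by 1.5 and 50 of 50 shifted by 2.5 in each direction, and called 13 of 17705 unchanged genes. With a noise SD of 0.492, that of a ratio if the difference between probe sets of a gene is all noise, it recovered 40 and 44 of 50 shifted up and down by 1.5, 50 and 48 of 50 shifted by 2.5, and called 595 of 17705 unchanged genes (3.36%). This wider simulation was added after seeing the data, and its spread, between probe sets on the same arrays, holds no variation between plants or labellings. In a step on 14460 genes a list shifted by 0.8 was found, and 2 of 39 unshifted lists lay outside the random range. The noise SD there was 0.3, below the SD of 0.846 of the ratios measured on both arrays. Recovery of smaller list shifts, or at that wider spread, was not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.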

Results

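Leaf RNA of 6-week-old rice was measured on 1 Affymetrix rice GeneChip per genotype, the control 9311, an indica variety, and 9311 carrying the LRK1 transgene, titled LRK1 060615 in the labels. LRK1 is a leucine-rich repeat receptor-like kinase gene of rice. Leaves of 10 plants per genotype were taken, without treatment. The 57258 probe sets other than controls had a median log2 signal of 5.21 on the control array and 5.56 on the transgenic array, and 47.5% and 52.5% of them reached the floor of 5.40. Across probe sets, which are not independent replicates, the log2 signals of the arrays correlated with a Pearson r of 0.889. With 1 array per genotype no difference has a replicate check, no p-value is given, and the number of arrays limits the precision. Every statement compares these arrays, not the genotypes in general, and every log2 ratio is LRK1 transgenic over control. No probe set could be tied to LRK1 by name, so the labels were not checked against the transgene's own signal.

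The comparison asked which leaf transcripts differed between LRK1 transgenic and control plants. Most listed genes of diterpenoid phytoalexin synthesis, pathogenesis-related proteins (largely chitinases) and cytosolic ribosomal proteins were at least 2-fold lower on the transgenic array. These lists hold only genes found by symbol or synonym, not every gene of their kind. The list medians of chlorophyll synthesis and auxin response lay above those of matched random lists, with 2 of 16 and 9 of 46 members at least 2-fold higher, or 1 and 3 with spike centring. Of 24426 probe sets at or above the floor on both arrays, 2042 (8.36%) were at least 2-fold higher in the transgenic array and 2430 (9.95%) at least 2-fold lower. A further 981 were above the floor only on the transgenic array and 617 only on the control array, a majority that turned round after quantile normalization (687 and 844), with spike centring (568 and 967) and with the floor at the 75th percentile (160 and 355). Among probe sets at or above the floor on both arrays, large differences were mostly decreases. There, 492 were at least 4-fold lower against 166 at least 4-fold higher, and 47 at least 16-fold lower against 14 at least 16-fold higher. Probe sets above the floor on 1 array only are not in these counts. Among genes, with 1 probe set each, 923 were higher and 1501 lower. In simulated arrays with the spread seen between probe sets of a gene, which leaves out variation between plants and labellings, 595 of 17705 unchanged genes passed the same rule.

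The split between higher and lower calls depended on the floor, the size rule and the scaling between arrays. Higher calls were the majority with the floor at the 25th percentile (5774 higher, 4577 lower, 55.8%) and with a 1.5-fold rule (5394 and 4692, 53.5%). Higher calls made up 45.7% of the called probe sets as deposited, 46.6% after quantile normalization, 39.9% after loess, 38.1% when centred on the median ratio of 0.08, and 19.3% when centred on the bacterial spike controls, whose median ratio was 0.34. Of 110 named genes past the size rule, 18 dropped below it with spike centring and 5 to 7 under each of the other scalings, and every one of these had been called higher or above the floor only on the transgenic array. Both centrings take a positive constant off every ratio, so only such calls could be lost under them. The direction is thus informative only for quantile normalization and loess, which lost 5 and 6 calls. PSI-H, CYCD5-2, RAB21, HSP24.1, NIP2-2, MT2B, OsPP2C73 and DREB1A dropped below the size rule under at least 1 scaling other than spike centring, and TPT, PPOX1, CYCD3-1, ABA8OX1, RR24, TUD1, YSL9, CML24, MPK2 and OsPP2C71 only with spike centring.

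**Figure D1:**
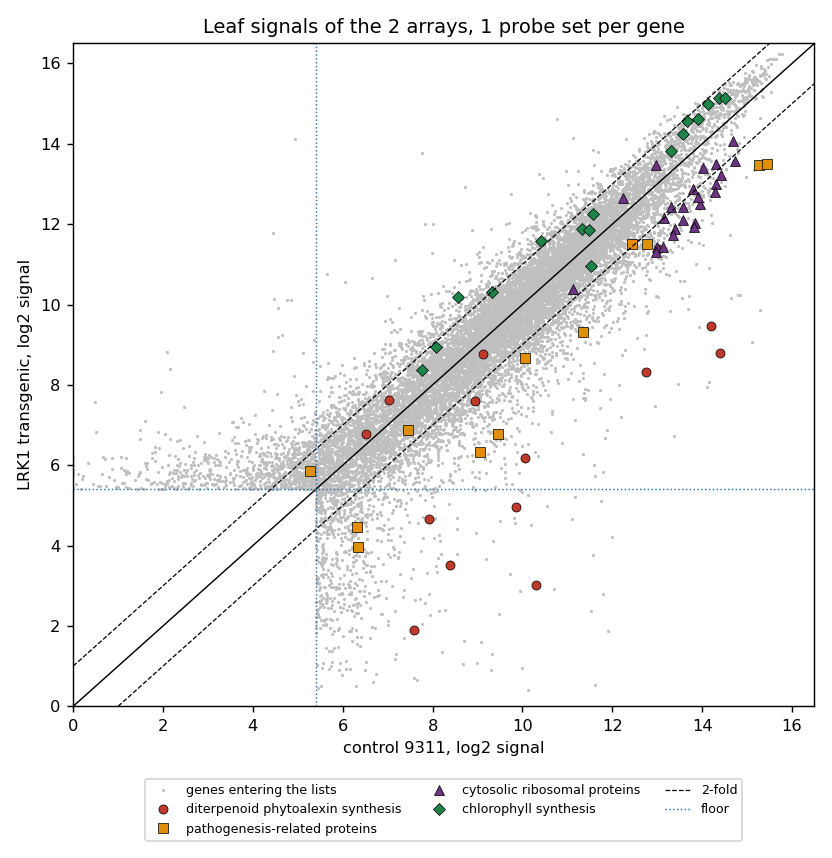
Log2 signal on the control 9311 array (x axis) and the LRK1 transgenic array (y axis), 1 point per gene entering the lists, with 4 lists coloured, the 2-fold lines dashed and the floor of 5.40 dotted. Phytoalexin, pathogenesis-related and ribosomal protein genes lie mostly under the diagonal, and as deposited 15 of 16 chlorophyll synthesis genes lie over it.

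Diterpenoid phytoalexins are antimicrobial compounds of rice, and their synthesis genes showed the lowest list median, -2.76. Of 14 genes used, 6 were at least 2-fold lower and 5 were above the floor only on the control array. In the phytocassane branch, the cytochrome P450 gene CYP71Z7 (LOC4329726) went from a log2 signal of 14.39 to 8.80, 48.2-fold lower. The diterpene cyclase gene CPS2 (LOC9266189) was 26.5-fold lower and KSL7 (LOC4329724) 21.7-fold lower. In the momilactone branch, CPS4 (LOC4335090) was at least 29.9-fold lower and CYP99A2 (LOC4335096) 14.7-fold lower. KSL10 (LOC4352248), a diterpene cyclase gene of oryzalexin synthesis, was at least 22.1-fold lower. The members CYP99A3 (-0.36), CYP76M6 (0.25) and KSL5 (0.59), named after their values were seen, did not pass the 2-fold rule. The list lay below all of 10000 random lists matched on signal, and 11 members were lower under each of the 4 other scalings. The related P450 gene CYP701A8 (LOC4341343), outside this list, was 23.6-fold lower.

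The pathogenesis-related list, made up largely of chitinases, which cut fungal cell walls, had a median of -1.32, below all of its random lists. Of its 12 genes 7 were at least 2-fold lower and none was higher. Cht10 (LOC4325148) was 6.64-fold lower and another chitinase gene (LOC4342115) 6.46-fold lower. PBZ1 (LOC4352491), the probenazole-inducible PR10 gene, named after its value was seen, was 3.88-fold lower from the control array's log2 signal of 15.45.

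**Figure D2:**
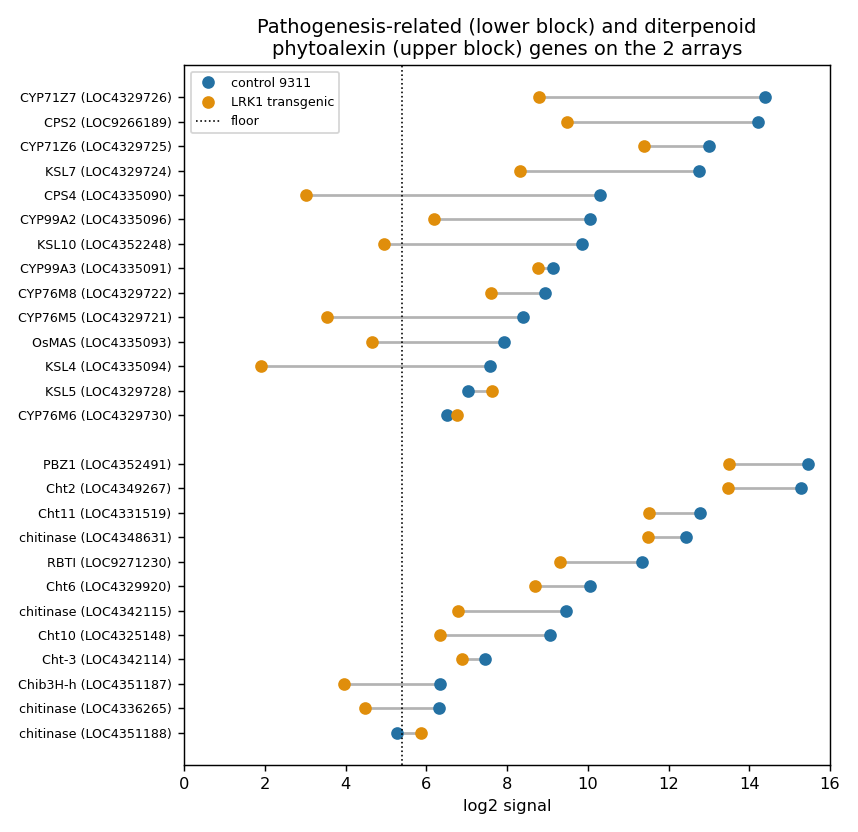
Log2 signal (x axis) of each gene of the diterpenoid phytoalexin (upper block) and pathogenesis-related lists (lower block) on the control 9311 array (blue) and the LRK1 transgenic array (orange), 1 value per array, with the floor of 5.40 dotted. Of 14 phytoalexin genes 12 have the lower signal on the transgenic array, as do 11 of 12 pathogenesis-related genes.

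Jasmonate is a hormone of wound and defence responses. AOS2 (LOC4332121), an allene oxide synthase gene of its synthesis, went from a log2 signal of 11.36 to 6.27 on the transgenic array, and the repressor gene JAZ5 (LOC4335698) was 9.53-fold lower. Of 31 jasmonate genes 8 were lower and none was higher, yet the list median of -0.13 was at percentile 13.3 of the random lists and did not stand apart. CYP71P1 (LOC4351945), the tryptamine 5-hydroxylase gene of serotonin synthesis, was 22.2-fold lower. In the phenylpropanoid and lignin list 8 of 25 genes were lower and none higher. The laccase genes LAC19 (LOC4351005) and LAC24 (LOC4351915) were at least 70.3-fold and 26.3-fold lower. The phenylpropanoid median of -0.39 was at percentile 0.880, but it turned to 0.28 with the floor at the 25th percentile and 0.23 on log2(signal + 16), and was -0.05 (percentile 25.2) over genes measured on both arrays, so the call was lost under these 3 settings.

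Cytosolic ribosomal protein genes were lower in the transgenic array as a group, with a median of -1.21 below all of the random lists. Of 24 genes 15 were at least 2-fold lower and none was higher. RPL39C (LOC9268459) was 3.68-fold lower and RPL7A-2 (LOC4347522) 3.47-fold lower. RPL18 (0.42) and RPL27 (0.52), named after their values were seen, had positive ratios. Proteasome subunit genes shifted less, with a median of -0.52 at percentile 0.320. Of the 16 proteasome genes 15 had negative ratios, with RPT1B (0.01, named after its value was seen) the exception, but only PBC1 (LOC4341637), 2.51-fold lower, passed the 2-fold rule. With spike centring 20 ribosomal and 6 proteasome genes passed it. The ratio of 3' to 5' signal was higher on the control array in each of 5 housekeeping probe set pairs, at 9.45 against 6.95 for actin and 3.87 against 2.16 for GAPDH. The difference was small for the other actin pair (16.4 against 16.2) and ubiquitin (0.831 against 0.782).

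Chlorophyll synthesis genes had a median of 0.70 at percentile 99.97, and as deposited 15 of 16 had positive ratios. The protochlorophyllide oxidoreductase gene PORA (LOC4337415) was 3.07-fold higher, and PPOX1 (LOC4327918), a protoporphyrinogen oxidase gene, was 2.25-fold higher but under 2-fold with spike centring. No other member passed the rule, and GSA (-0.56), named after its value was seen, was the member with a negative ratio. In the list of chlorophyll breakdown and senescence, the stay-green gene SGR (LOC4347672) was 2.30-fold lower and RCCR1 (LOC4348519), a red chlorophyll catabolite reductase gene, 2.12-fold lower, but the median of -0.51 over 5 genes was at percentile 7.87. Photosystem and antenna genes (0.56, percentile 92.1) and Calvin cycle genes (0.57, percentile 86.2) did not stand apart. PSI-H (LOC4339593), a photosystem I subunit gene, was 2.04-fold higher, a call lost under each of the 4 other scalings. FNR (LOC4342399), a ferredoxin-NADP reductase gene, was 4.98-fold lower. The other listed genes of this enzyme, LFNR1 (0.66) and FNR (LOC4334338, 0.42), named after their values were seen, had positive ratios as deposited. The triose phosphate translocator gene TPT (LOC4326365) was 2.31-fold higher.

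**Figure D3:**
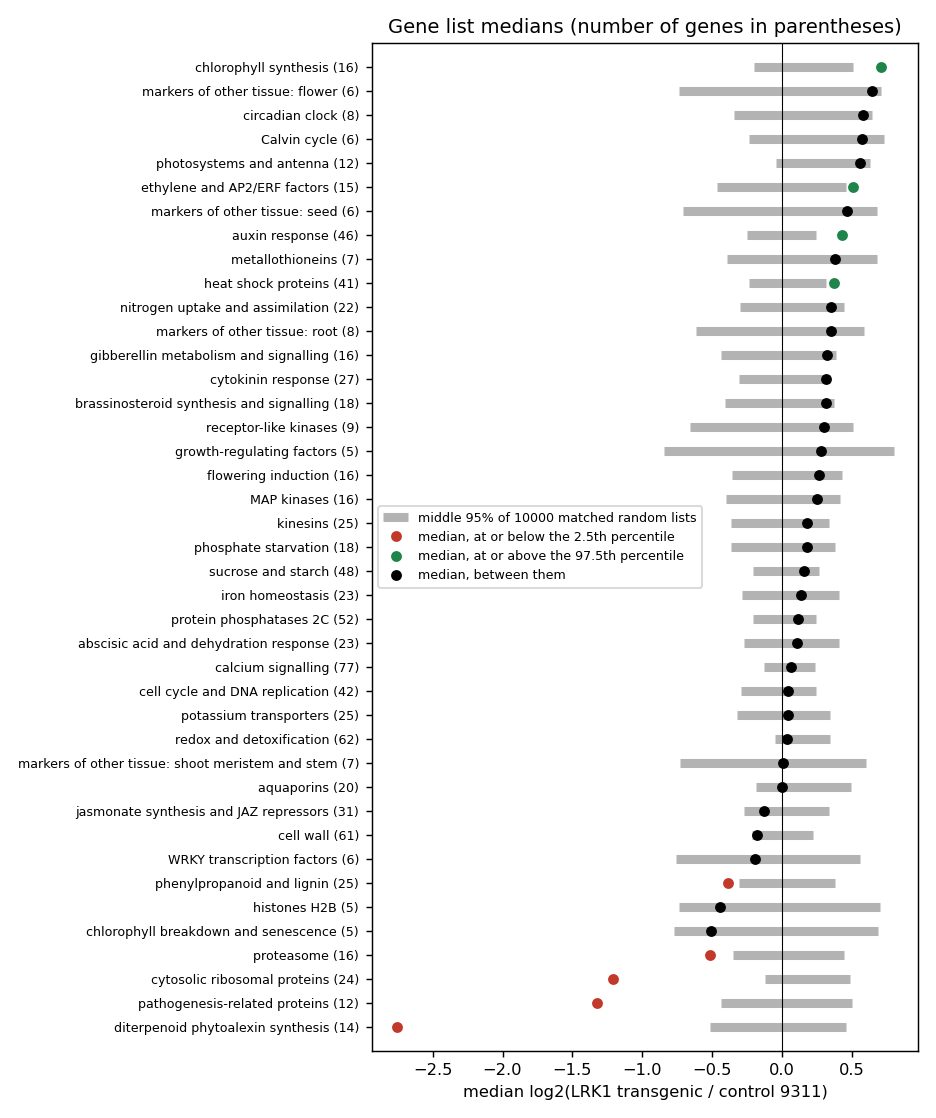
Median log2 ratio (LRK1 transgenic over control 9311, x axis) of each of the 41 gene lists as deposited, with the number of genes in parentheses and grey bars for the middle 95% of 10000 random lists matched on signal. The phytoalexin list is lowest at -2.76 and the chlorophyll synthesis list highest at 0.70; medians near 0 change sign under other scalings.

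Auxin response genes had a median of 0.43 at percentile 99.99, with 9 of 46 at least 2-fold higher and 3 lower. Under spike centring the median was 0.17, with 3 members higher and 5 lower. The percentile there was 100, but spike centring takes the same constant off the random lists, so this is little test of the call. The repressor gene IAA2 (LOC4326775) was 3.62-fold higher and the auxin response factor gene ARF16 (LOC4327785) 2.67-fold higher. PIN3A (LOC4326565), of the auxin efflux carriers, was 4.49-fold lower and GH3.2 (LOC4326893), of auxin conjugation, 3.86-fold lower. Cytokinin genes had a median of 0.32 at percentile 96.2, which did not stand apart, although they did under all 11 alternatives, at percentiles from 98.3 to 99.8. Of 27 cytokinin genes 7 were higher and 1 lower. LOG (LOC4324445), which activates cytokinin, was 3.21-fold higher, the response regulator gene RR24 (LOC4328516) 2.47-fold higher and LOGL1 (LOC4327684) 2.60-fold lower. With spike centring the cytokinin count turned to 1 higher and 2 lower.

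The ethylene and AP2/ERF list had a median of 0.51 at percentile 98.6, set by a member below the floor on the control array, and the call was lost under 4 of 11 alternatives, among them quantile normalization (percentile 96.3). Of its 15 genes 2 were higher and 2 lower, or 1 and 3 with spike centring. EIL1B (LOC4332697), an ethylene-insensitive3-like factor gene, was at least 82.2-fold lower and the ethylene synthesis gene ACS2 (LOC4336750) 2.07-fold lower. The cold-response factor genes DREB1B (LOC4347618) and DREB1A (LOC4347620) were 2.56-fold and at least 2.08-fold higher, DREB1B from a control signal near the floor (5.73). Heat shock genes had a median of 0.37 at percentile 99.0, but the members past the 2-fold rule went mainly the other way, with 1 of 41 higher and 4 lower, or 0 and 5 after loess or centring on the median ratio and 0 and 7 with spike centring. HSP24.1 (LOC4330786) was 2.04-fold higher, under 2-fold with each of the 4 other scalings. The heat shock factor genes HSFA4D (LOC4339409) and HSFB1 (LOC4347259) were 5.55-fold and 5.25-fold lower. The heat shock call was lost after loess (percentile 95.7), without probe sets that can bind several transcripts (90.9) and with the median over each gene's probe sets (92.9).

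Gibberellin genes (0.32, percentile 94.8), brassinosteroid genes (0.31, 94.8), circadian clock genes (0.58, 94.6) and flowering genes (0.26, 85.4) did not stand apart, and with spike centring the brassinosteroid (-0.04) and flowering (-0.06) medians turned negative. The gibberellin call changed without probe sets that can bind several transcripts (percentile 98.4), the brassinosteroid call after quantile normalization (97.7) and loess (97.6), and the clock call with the median over each gene's probe sets (98.2). SLRL1 (LOC4325922), a DELLA-like gene, was 3.44-fold higher, from a control signal near the floor (5.55), and the P450 gene CYP701A19 (LOC4341347) was 3.06-fold lower. D11 (LOC4336116), a P450 gene of brassinosteroid synthesis, was at least 4.74-fold higher, and TUD1 (LOC4332159) 2.47-fold higher. PRR37 (LOC4344399), a clock and heading date gene, was 3.69-fold higher. The floral MADS-box gene MADS14 (LOC4334140) was 4.05-fold higher, on a probe set that can bind several transcripts. Abscisic acid and dehydration genes (0.11, percentile 55.7) held 3 higher and 6 lower members of 23, or 1 and 6 when centred on the median ratio and 0 and 6 with spike centring, where all higher calls were lost. ABA8OX1 (LOC9269675), which breaks abscisic acid down, was 2.22-fold higher and RAB21 (LOC4350454) 2.09-fold higher, while the dehydration genes rab25 (LOC4326935) and RAB16B (LOC4350453) were 4.37-fold and 3.87-fold lower. With the median over each gene's probe sets the abscisic acid median was -0.33 at percentile 2.08.

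Sugar and nitrogen genes moved in both directions. In the sucrose and starch list (median 0.16, percentile 85.1; -0.17 with spike centring) 7 of 48 genes were higher and 8 lower, or 4 and 8 with spike centring, and with the floor at the 25th percentile the list stood apart at percentile 99.5. The sucrose synthase genes SUS6 (LOC4331252) and SUS5 (LOC4335447) were 5.18-fold and 4.24-fold higher, from control signals near the floor (5.79 and 5.73). SUS1 (LOC4333062) was at least 21.7-fold lower and the sugar transporter gene SWEET15 (LOC4329464) 8.12-fold lower. In the nitrogen list (0.35, percentile 91.7) the ammonium transporter gene AMT1-2 (LOC4330008) was 2.84-fold higher, AMT2-3 (LOC4327433) 2.77-fold lower and GDH3 (LOC4330164), of glutamate dehydrogenase, at least 13.9-fold lower. In the phosphate list (0.18, percentile 78.4, and -0.13 with spike centring) the transporter genes PHO1-2 (LOC4331090) and PHT1-1 (LOC4331635) were 4.41-fold and 2.67-fold higher. None of its genes was 2-fold lower as deposited. When centred on the median ratio 2 were lower, after quantile normalization 1, and after loess or spike centring 3.

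Cell wall genes had a median of -0.18 at percentile 4.99, with 4 of 61 higher and 5 lower, or 3 and 13 with spike centring, and stood apart with the median over each gene's probe sets (percentile 1.62) and over genes measured on both arrays (1.53). Expansins loosen cell walls. The beta-expansin genes EXPB2 (LOC4349348) and EXPB11 (LOC4330213) were at least 5.42-fold and 4.14-fold higher. EXPB7 (LOC4331300) was 5.15-fold higher, from a control signal near the floor (5.48). EXLA3 (LOC4343213) was 7.67-fold lower and EXPA10 (LOC4336776) 5.09-fold lower. Redox and detoxification genes (0.03, percentile 11.7; -0.31 with spike centring) held 1 higher and 9 lower members of 62. GST-I (LOC4325710), of the glutathione transferases, was 3.24-fold higher, a peroxidase gene (LOC4344277) 13.6-fold lower and the catalase gene CAT-A (LOC4328073) 4.27-fold lower. Aquaporin genes (median 0.00) held 1 higher and 6 lower of 20, or 0 and 6 after loess or either centring, with PIP2-5 (LOC4343121) 5.62-fold and TIP2-1 (LOC4330207) 4.02-fold lower and NIP2-2 (LOC4340558) 2.11-fold higher. The aquaporin list stood apart at -0.29 (percentile 2.19) after quantile normalization and -0.37 after loess.

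Among potassium transporters (median 0.04, percentile 53.5; -0.30 with spike centring) HAK18 (LOC4347862) was 3.90-fold and the channel gene KCO1 (LOC4334137) 2.65-fold higher, and HAK17 (LOC4347211) and HAK1 (LOC4335729) were 6.85-fold and 3.44-fold lower. Iron homeostasis genes (0.14, percentile 60.8; -0.20 with spike centring) included IDEF1 (LOC4344415) and YSL9 (LOC4336545), 2.63-fold and 2.38-fold higher, and YSL5 (LOC4335677) and Nramp1 (LOC4342862), 3.51-fold and 3.35-fold lower. Among calcium signalling genes (0.06, percentile 53.2; -0.27 with spike centring) the kinase gene CIPK8 (LOC4326419) was 3.84-fold and the calmodulin-like gene CML24 (LOC4344304) 2.49-fold higher, and the exchanger gene CAX2 (LOC4333044) and CML8 (LOC4348517) were 3.60-fold and 2.84-fold lower. For MAP kinases (0.25, percentile 86.1; -0.09 with spike centring) MPK2 (LOC4344698) was 2.43-fold higher and MPK13 (LOC4328223) 3.98-fold lower. Protein phosphatases 2C (0.11, percentile 77.8, and -0.23 with spike centring) held 3 higher and 3 lower members. These counts were 1 and 3 after loess or centring on the median ratio, and 0 and 7 with spike centring. Members were OsPP2C71 (LOC4348468) and OsPP2C73 (LOC4349568), 2.47-fold and 2.07-fold higher, OsPP2C16 (LOC107276004), at least 8.81-fold lower, and OsPP2C21 (LOC4329930), 2.64-fold lower. Metallothionein genes (0.37, percentile 67.7) included MT2B (LOC4326409), 2.04-fold higher, and MT1B (LOC4332487), 3.47-fold lower.

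Growth and cell division lists did not stand apart. Cell cycle and DNA replication genes (0.04, percentile 63.0; -0.29 with spike centring) held 2 higher and 2 lower members of 42, or 1 and 4 when centred on the median ratio and 0 and 5 with spike centring. The cyclin genes CYCD3-1 (LOC4340499) and CYCD5-2 (LOC4352668) were 2.15-fold and 2.05-fold higher, CYCD6-1 (LOC4343569) was 4.81-fold lower and PCNA (LOC4331062), of the replication clamp, 2.97-fold lower. Kinesin genes (0.18, percentile 85.2; -0.16 with spike centring) included KIN14L (LOC4340497), 3.10-fold higher, and KIN7J, at least 3.19-fold higher. Of 5 growth-regulating factor genes (0.28, percentile 70.4) GRF4 (LOC4330436) was at least 2.69-fold higher. None of 5 histone H2B genes (-0.45, percentile 7.97) passed the 2-fold rule as deposited, although 1 was lower with spike centring, and H2B.5 (LOC4324504), the brightest, had a ratio of 0.29. None of 6 WRKY factor genes (-0.20, percentile 30.9) passed it as deposited, although 2 were lower with spike centring, and WRKY76 (LOC4347069) had a ratio of 0.14. Among 9 receptor-like kinase genes (0.30, percentile 88.6; -0.04 with spike centring) CR4 (LOC4333525) was at least 2.36-fold higher.

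Markers of other tissues did not stand apart. The medians were 0.64 for flower (percentile 96.4), 0.46 for seed (90.4) and 0.35 for root (86.5). That for shoot meristem and stem was 0.00 (percentile 49.7, and -0.33 with spike centring). How well each list marks its tissue was not tested. The seed list stood apart on log2(signal + 16), at percentile 97.6. The YABBY factor gene YAB2 (LOC4333584) was 7.87-fold higher, LAX1 (LOC4327431), of axillary meristem formation, at least 2.18-fold lower, the floral gene MADS2 (LOC4325001) 2.40-fold lower and OsCASP1 (LOC4337453), of the root Casparian strip, above the floor only on the transgenic array, at a log2 signal of 6.72. The seed storage glutelin gene GLUA-2 (LOC4348563), the brightest of its list, had a ratio of 0.48.

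Outside the lists, the bZIP factor gene TGAL1 (LOC9266109) was 7.91-fold higher, the blue light receptor gene PHOT1A (LOC4351240) 5.92-fold, OsCASPL2C2 (LOC4328486) 5.42-fold, the zinc finger gene OsC3H54 (LOC4344566) 4.97-fold, the 4-coumarate-CoA ligase-like gene 4CLL7 (LOC4342925) 4.48-fold and the BURP domain gene BURP2 (LOC4338119) 4.34-fold. Control signals of these genes are not given here, and folds from control signals near the floor are less certain. RLA1 (LOC4338669), of the AP2-type factors, and XBOS36 (LOC4339988) were at least 5.96-fold and 4.26-fold higher. The BURP domain gene BURP16 (LOC4348595) was 31.9-fold lower and OsCASPL1D1 (LOC4343098) 11.9-fold lower. Of the 41 lists with a value, 9 stood apart, 5 lower and 4 higher, where lists of randomly drawn genes would give 2.05. That number leaves out that members of a list can vary together and that lists share genes. It also holds no variation between plants or arrays, so it is not the number to be had without a genotype effect. Among lists that did not stand apart, some medians near 0 changed sign with the scaling. Those of redox and aquaporin genes turned negative under all 4 other scalings, and those of cell cycle, calcium and potassium genes under every one but quantile normalization. Abscisic acid and iron medians turned negative under every one but centring on the median ratio, and the meristem marker median when centred on the median ratio or on the spikes. Phytoalexin, pathogenesis-related, ribosomal, proteasome, chlorophyll synthesis and auxin lists kept their call under all 11 alternatives. Both centrings among these take the same constant off a list and its random lists, so they test the calls little.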

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

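The test of tissue markers, the spike centring among the scalings, and the matching on genomic span were chosen only after the list results were seen, and the tests of neighbouring genes without the phytoalexin list and without shared probe sets only after the count of adjacent pairs.

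Control probe sets for the rice blast fungus Magnaporthe, which lie outside the comparison of rice genes, passed the floor of 5.40 on the transgenic array and not on the control array in a pair of cases, 6.22 for the 5' probe set of its actin (control 5.16) and 5.81 for the 3' probe set of its GAPDH (control 1.64). Neither reaches 2 times the floor, which the comparison of rice genes asks of a signal on 1 array only. The other 8 of the 10 Magnaporthe probe sets were below the floor on both arrays, among them the middle probe set of GAPDH, listed at 0 on the control array and at 4.91 on the transgenic array. Of the 10, 9 were higher on the transgenic array, with a median log2 ratio of 1.01, mostly between background signals. Low rice signals were higher there too, with a 25th percentile of 3.35 against 2.94, and 230 rice probe sets listed at 0 against 883. Rice probe sets of like control signal were not compared, so an excess of the Magnaporthe ratios over background cannot be judged. The source of these signals was not tested.

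The phytoalexin genes were the lowest list, at -2.76. The scaling differences tried are argued against, since the highest median over 4 other scalings was -2.72. Both centrings take a positive constant off every ratio and could only lower the median, so this rests on quantile normalization (-2.72) and loess (-2.83). Probe sets that bind several transcripts are argued against, since the median without them was -3.14 over 13 genes. More root, stem or flower tissue in the control leaves stays open, since the lowest percentile of those 3 marker lists was 49.7, not the low value such tissue would give, but the lists hold only 6 to 8 measured genes and their members go both ways. The 49.7 is that of the meristem and stem list. Its member OSH45 was bright in both leaf samples (12.85 and 12.81), so this list may not mark such tissue. The LRK1 transgene stays open as a biological explanation, since 1 array per genotype leaves it confounded with the plants and the array.

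The cytosolic ribosomal protein list, at -1.21, was lower while the control array had the higher 3' to 5' ratios, by little for ubiquitin and the other actin pair. A scaling difference that follows signal is argued against, since after loess the median was -1.45, outside the range of its random lists of -0.31 to 0.28. RNA of the control more biased to the 3' end, which favours short genes, is argued against as a trend with genomic span, since random lists matched on signal and span had a median of 0.16 and a range of -0.22 to 0.46. Genomic span includes introns, so it is not transcript length, and an effect of RNA integrity on particular transcripts stays open. The LRK1 genotype stays open too, untested with 1 array per genotype.

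Called genes were neighbours more often than random placement gave, with 335 adjacent pairs called in the same direction (101 both higher, 234 both lower) against a random median of 276 and an upper bound of 305, in the gene order of assembly ASM3414082v1. The phytoalexin list's genes alone are argued against, since 326 pairs were left without them (random 273 and 303). Other lower genes of those clusters, such as LOC4329723 and LOC4335099, stayed in, so the clusters as a whole were not tested. Shared probe sets of gene copies are argued against, since 282 pairs were left without probe sets that can bind several transcripts (random 242 and 270). A chromosome segment of other origin in one of the genotypes cannot be told apart: the most called genes in a window of 50 measured genes was 22, against a random median of 20 and an upper bound of 23. The bound set beforehand would have excluded a segment for missing that upper bound, and it was wrong, since a short segment or one with few called genes need not fill a window. Neighbouring genes changing together may thus go beyond the phytoalexin list's genes, with the LRK1 genotype as an untested explanation.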

How the results depend on the processing

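Spike centring and span matching were chosen after seeing the data; the other alternatives were fixed before. With the floor at the 25th percentile, 5774 probe sets were higher, 4577 lower, 4587 above the floor only on the transgenic array and 3042 only on the control array, and with the floor at the 75th percentile these were 779, 1062, 160 and 355. The floor at the 25th percentile thus turned the majority to higher, as did a 1.5-fold rule, with 5394 higher and 4692 lower, while a 3-fold rule gave 469 and 923, and counting genes 923 and 1501. Spike centring gave 967 higher and 4043 lower, with 568 and 967 on 1 array only. The floors, size rules and counting unit change what is counted by construction; for spike centring the cause was not tested beyond the shift of 0.34 it takes off every ratio. The other 27 counts, among them the number of lists standing apart, were within 1.5 times the value as deposited, although the only-on-1-array majority turned round after quantile normalization (687 transgenic, 844 control). The phenylpropanoid median turned from -0.39 to 0.28 with the floor at the 25th percentile and 0.23 on log2(signal + 16), and the cause was not tested. Of the other list medians under an alternative, 371 moved by no more than 1 SD of the random lists and 70 by more; H2B genes, the tissue markers and growth-regulating factors had too few genes for a value under 1 or 2 alternatives. Of the named genes' ratios, 596 moved by no more than the spike SD of 0.220, 177 by more, and none past the 2-fold rule changed sign. LRK1 alternatives were not run, since no probe set was tied to it. Signals near the floor limit the bounds. No paired analysis was possible because each genotype has 1 array.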

Other observations

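The lists and single genes given here were all chosen after the ratios were seen, so their percentiles are not independent evidence.

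Genes of protein folding and glycosylation in the endoplasmic reticulum were lower on the transgenic array, with a median log2 ratio of -0.94 below all of 10000 matched random lists. Of 26 genes 12 were at least 2-fold lower and none was higher. The protein disulfide isomerase genes PDIL1-4 (LOC4327971) and PDIL1-1 (LOC4350002) were 4.21-fold and 3.92-fold lower, the chaperone gene ERDJ3B (LOC4337860) 3.78-fold, OST48 (LOC4342702), of the oligosaccharyl transferase, 3.17-fold and the chaperone gene BIP1 2.21-fold lower. Mitochondrial import, channel and succinate dehydrogenase genes had a median of -0.74 at percentile 0.0300, with 6 of 16 lower, among them the import gene TIM9 (LOC4352583), 3.16-fold, and the channel gene VDAC1 (LOC4346851), 2.85-fold.

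Tryptophan and serotonin synthesis genes had a median of -0.74 at percentile 0.210, with 4 of 12 lower and 2 higher. CYP71P1 (LOC4351945) was 22.2-fold lower and the anthranilate synthase gene ASA2 3.92-fold lower, while SNAT2 (LOC4344423), of serotonin acetylation, was 2.99-fold higher. Tubulin and actin genes had a median of -0.56 at percentile 0.920, with 3 of 13 lower, TUBB2 (LOC4331315) by 3.66-fold and ACT1 (LOC4333919) by 2.43-fold. Plastid protease and import genes (0.22, percentile 61.0), homeobox leucine zipper genes (0.21, percentile 88.6) and beta-glucosidase genes (0.21, percentile 84.6) did not stand apart, and germin-like genes were too few, with 4 used.

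In the phytocassane cluster, an unnamed neighbour, LOC4329723, between CYP76M8 (2.52-fold lower) and KSL7, went from a log2 signal of 11.16 to 5.21, at least 54.5-fold lower. Next to the momilactone genes, LOC4335099 was at least 5.13-fold lower, and ARP9 (LOC4335089), beside CPS4, had a ratio of -0.05.

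Some genes with wide differences had no name in the tables used. LOC4329983 was below the floor on the control array (4.93) and at 14.12 on the transgenic array, at least 423-fold higher, and LOC4333700 was at least 83.6-fold higher. LOC4351246 was 63.5-fold higher on both measured signals, from 7.77 to 13.76, and LOC4348633 100-fold lower, from 13.37 to 6.72.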
